A study of Mus musculus with 9 samples.

How the data were processed

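RNA was sequenced from 9 libraries of C57BL/6J mouse tissue, 3 of immature cartilage (ImC, immature chondrocytes), 3 of mature cartilage (MatC, mature chondrocytes) and 3 of bone (Bone, osteoblasts). Groups and replicate numbers were taken from the library titles. Per the labels' protocols, very small RNA inputs were purified, treated with DNase and amplified for 1 round before an Illumina TruSeq library preparation. That kit does not mark strand, so reads of genes that overlap on opposite strands could not be told apart. The labels name neither an anatomical site nor a stage.

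The deposited table of raw counts holds whole reads per gene symbol for 43472 genes, with 0 entries that name no gene. Per the submitters' processing notes, the tools included Trimmomatic 0.30, TopHat2, Bowtie2, HTSeq and edgeR with the mm10 genome; the role and order of each tool were not given in the sources used here. The authors' second deposited table holds 13302 genes as normalized values rounded to whole numbers, a score in which each library is scaled by 1 factor. It was used only to read those factors back, from genes with more than 2000 raw counts, for an alternative scaling. The factors were 0.918 to 1.04 times those of DESeq2's size-factor method. All per-sample columns were mapped to a sample.

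The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the raw counts. Genes were kept by filterByExpr with a minimum count of 10, which left 14257 genes holding at least 99.8% of the counts of each library. Libraries were scaled by trimmed mean of M values (TMM) factors, and all 9 libraries entered 1 fit with a mean per group. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and genes with an adjusted p under 0.05 were called. Log2 fold changes carry a standard error (SE) computed as the absolute log2 fold change over the square root of F. Levels are counts per 1e6 reads (CPM) with TMM factors, as mean ± SD over 3 libraries. The comparisons were MatC against ImC, Bone against MatC and Bone against ImC. From these calls, genes were classed as above both, below both or intermediate in MatC. The position of MatC between ImC (0) and Bone (1) was computed on the log2 scale for genes called between Bone and ImC with an absolute log2 fold change of at least 1.

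Where the lower group held 0 reads, a fold is given against a floor of 3 reads over the group, as at least that many fold; the floor was 0.0649 CPM in ImC, 0.097 in MatC and 0.0626 in Bone. Where it held 1 to 3 reads, the ratio of reads pooled over the libraries of each group, each over the summed scaled library sizes, is given with its 95% counting interval. It can differ from the ratio of the mean CPM. Intervals and floors cover counting error only, because amplified reads are not independent molecules.

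In all, 21 gene lists were fixed before the data were examined. They covered skeletal cell types (immature chondrocyte, hypertrophic chondrocyte, osteoblast), other cell types (perichondrium, tendon and fibroblast; endothelial; osteoclast; macrophage and leukocyte; erythroid; skeletal muscle), and the cell cycle. Pathway lists covered hedgehog, Wnt targets and inhibitors, BMP and TGF-beta, FGF, mineralization, matrix proteases and inhibitors, collagen processing, glycosaminoglycan synthesis, hypoxia and glycolysis, endoplasmic reticulum stress and secretion, and immediate early and stress genes. Some genes are in more than 1 list; Alpl, Ibsp and Spp1 are in the hypertrophic, osteoblast and mineralization lists. Each list was tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the 21 lists of a comparison, and again with an estimated correlation.

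Genes were named by a rule fixed at the same time: 18 marker genes, the 8 largest changes per comparison and direction among called genes whose groups did not overlap and whose higher group averaged at least 20 CPM, and up to 3 called members per list with the smallest p plus called members that went against their list's median. The rule also took the 10 leading genes above and below both, and 6 intermediate genes per direction. Genes named outside the rule are stated to be so, and some single genes are not reported here. Gene coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 denotes; 13400 of the 14257 tested symbols (94%) matched it.

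The procedure was tested on simulated counts for 14257 genes with the real means and library sizes. Of genes changed 2-fold, 4-fold and 8-fold, the test recovered 0%, 43.3% and 74.2% for MatC against ImC with 2 false calls, 1.49%, 34.3% and 65.2% for Bone against MatC with 5 false calls, and 0%, 29.9% and 63.6% for Bone against ImC with 3 false calls. Only 67, 67 and 66 genes were changed at these folds in each comparison, far fewer than were called in the data. Adjusted p-values are stricter when few genes change, so these rates need not hold in the real tests. In the simulated setting small changes were mostly missed.

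Alternatives were other scalings (size factors, upper quartile, library size only), DESeq2 1.42.0, limma-voom, other count filters, a test against a 1.5-fold change, an adjusted p of 0.01, only the 2 groups compared, a replicate block, and each library left out in turn. Alternatives added after seeing the data left out mitochondrial genes, used the authors' factors, or left out replicate 3 of both ImC and MatC.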

Results

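The data set measured gene expression by RNA sequencing in immature cartilage, mature cartilage and bone of the mouse, with 3 libraries per tissue. Total counts ran from 7913684 in Bone replicate 2 to 23159547 in MatC replicate 2. Mitochondrially encoded genes took 44.1% ± 11.6 (SD, n = 3) of the counts in ImC, 61.7% ± 25.1 in MatC and 8.01% ± 0.84 in Bone. MatC replicate 3 stood apart, with 82.3% mitochondrial counts, 14940 genes with a read against 17535 or more in each other library. There 3 reads equalled 0.849 CPM, against at most 0.257 CPM in the other libraries. Rank correlations between replicates across genes were 0.974 to 0.982 in Bone, 0.842 to 0.959 in ImC and 0.85 to 0.917 in MatC. No pair of replicates agreed within sampling noise. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples only. The 3 groups share 1 estimate of that spread, so p-values for MatC against ImC also draw on the closer Bone replicates.

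**Figure D1:**
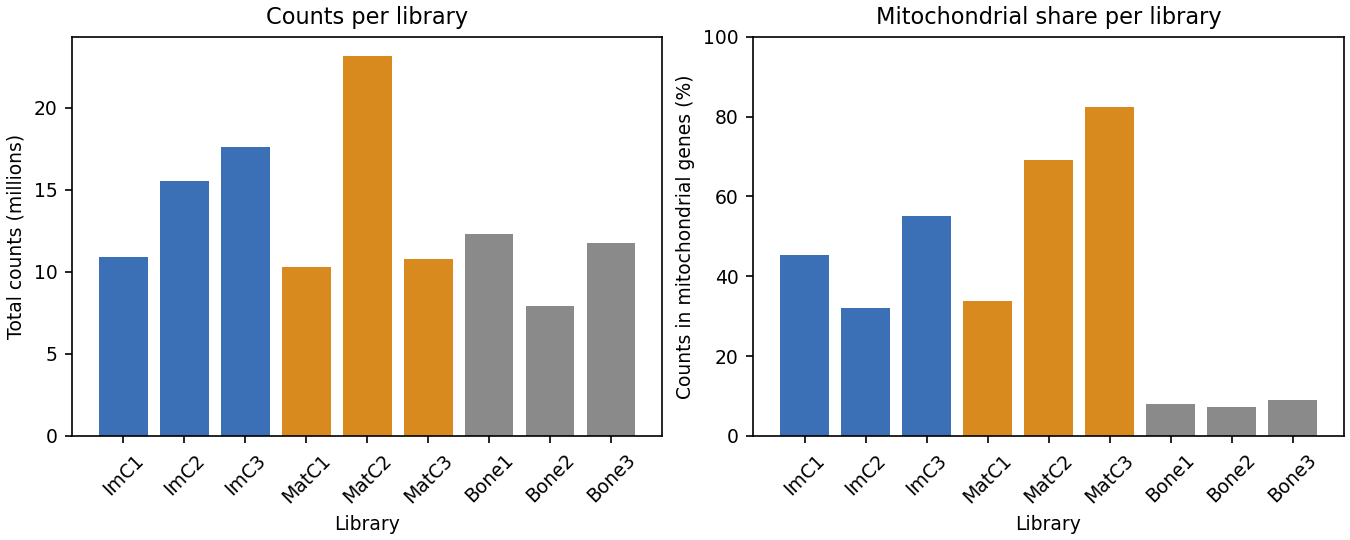
Total counts (left) and the percentage of counts in mitochondrially encoded genes (right), 1 bar per library. Bone libraries hold 7.24% to 8.91% mitochondrial counts, and cartilage libraries hold 32% to 82.3%.

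MatC was compared with ImC to ask what changed as cartilage matured. Hypertrophy genes were among the genes that rose. Col10a1, the collagen of hypertrophic cartilage (chromosome 10, 34389981 to 34397085, GRCm38), rose from 0.541 ± 0.181 CPM in ImC to 2170 ± 2244 CPM in MatC (SD, n = 3), a log2 fold change of 11.97 ± 1.04 (SE, adjusted p = 0.000749). Ihh, a hedgehog ligand of prehypertrophic chondrocytes (chromosome 1, 74945315 to 74951672), rose by 8.46 ± 0.80 on the log2 scale (adjusted p = 0.000973), and the transcription factor Mef2c (chromosome 13, 83504034 to 83667080) rose by 3.79 ± 0.32 (adjusted p = 0.000677). Genes used by osteoblasts rose as well: Sp7, a transcription factor of bone formation, by 5.43 ± 0.75, the phosphatase Alpl by 7.99 ± 0.74 and the bone sialoprotein Ibsp (chromosome 5, 104299171 to 104311469) by 7.96 ± 1.18 (adjusted p = 0.0041, 0.000849 and 0.00553). Col10a1 stood at 816.9, 933.1 and 4760 CPM in MatC replicates 1, 2 and 3, and its log2 fold change was 10.68 without MatC replicate 3. Without MatC replicate 2, Alpl and Ibsp rose by 7.29 and 6.62, and without ImC replicate 1, Ihh and Sp7 rose by 9.54 and 6.85.

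The matrix genes Col2a1 and Acan were not called between the cartilage groups. Col2a1, the main cartilage collagen, averaged 7188 ± 2095 CPM in MatC and 8919 ± 752 CPM in ImC (adjusted p = 0.69), and the proteoglycan Acan averaged 1040 ± 449 and 1113 ± 241 CPM (adjusted p = 0.918). Sox9, the transcription factor that sets chondrocyte identity, had a log2 fold change of -0.84 ± 0.42 (adjusted p = 0.248). Its partner Sox5 fell by 2.14 ± 0.30 on the log2 scale (adjusted p = 0.00444). Sox6 fell by 1.38 ± 0.35 (adjusted p = 0.0419). That call ended without ImC replicate 1 or 2, MatC replicate 1 or 2 or any 1 Bone library, with adjusted p up to 0.165 over all settings tried. Runx2, a master regulator of osteoblasts, had a log2 fold change of 2.94 ± 0.81 (adjusted p = 0.0543) and Col1a1, the main bone collagen, 3.77 ± 1.10 (adjusted p = 0.0643); neither was called.

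Of the hypertrophic chondrocyte genes, 11 of 21 tested rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 1.08e-11, and adjusted p = 0.0273 with an estimated correlation). Of the osteoblast genes, 15 of 29 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 1.08e-11, and adjusted p = 0.183 with an estimated correlation). Dlx3 and Phex rose by 6.90 ± 0.73 and 6.77 ± 0.86 on the log2 scale. Of the mineralization genes, 7 of 16 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 7.83e-06, and adjusted p = 0.054 with an estimated correlation). Smpd3, a sphingomyelinase needed for mineral deposition, rose by 4.89 ± 0.62. Dlx3 and Phex rose by 6.21 and 5.46 without MatC replicate 2, and Smpd3 by 5.51 without ImC replicate 1. Of the matrix proteases and inhibitors, 4 of 16 rose (6 adjusted over the list alone; camera adjusted p = 0.00448, and adjusted p = 0.392 with an estimated correlation). The collagenase Mmp13 had 1 read in all of ImC and a MatC to ImC ratio of 1430 (95% counting interval 256 to 56600). Of the immature chondrocyte genes, 6 of 25 fell and 0 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.00448, and adjusted p = 0.446 with an estimated correlation). That list was not called without MatC replicate 2 (adjusted p = 0.256, and 3.01e-05 to 0.256 over all settings). Of the cell cycle genes, 4 of 23 fell (4 adjusted over the list alone; camera adjusted p = 3.87e-05, and adjusted p = 0.392 with an estimated correlation). Tpx2 and Cenpf fell by 1.65 ± 0.28 and 1.98 ± 0.34 on the log2 scale.

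Markers of other cell types were higher in MatC beside the osteoblast genes. Endothelial genes rose in 11 of 18 cases (15 adjusted over the list alone; camera adjusted p = 2.68e-07), macrophage and leukocyte genes in 7 of 15 (12; 7.83e-06), osteoclast genes in 5 of 14 (8; 0.00103) and erythroid genes in 2 of 10 (3; 0.00103), each with adjusted p = 0.392 with an estimated correlation. Perichondrium, tendon and fibroblast genes rose in 9 of 26 cases and fell in 1 (10 and 1; camera adjusted p = 0.000171, and adjusted p = 0.392 with an estimated correlation). Skeletal muscle genes rose in 3 of 15 cases (4; camera adjusted p = 0.000171, and adjusted p = 0.417 with an estimated correlation). The endothelial receptor Tek had 1 read in ImC and a ratio of 547 (95% counting interval 97.5 to 21700). The complement gene C1qa, with 0 reads in ImC, was at least 51.5-fold higher. These levels differed between MatC libraries: the endothelial gene Cdh5 stood at 14.8, 28.1 and 0.566 CPM in replicates 1, 2 and 3, and Col1a1 at 1487, 7726 and 164 CPM.

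Among signalling lists, BMP and TGF-beta genes rose in 6 of 26 cases and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00471, and adjusted p = 0.401 with an estimated correlation). Bmp8a rose by 7.41 ± 0.71, while the joint-forming factor Gdf5 fell by 4.59 ± 0.81 on the log2 scale. The values were 8.48 for Bmp8a without ImC replicate 1 and -3.47 for Gdf5 without ImC replicate 2. Hypoxia and glycolysis genes fell in 3 of 25 cases (3; camera adjusted p = 0.0395, and adjusted p = 0.569 with an estimated correlation). The BMP and TGF-beta call ended without ImC replicate 3 (adjusted p = 0.0843, and 0.000499 to 0.0843 over all settings). The hypoxia call ended without ImC replicate 2, MatC replicate 1 and MatC replicate 2 (adjusted p = 0.537, 0.104 and 0.312, and 3.07e-05 to 0.537 over all settings). The remaining lists were not called: Wnt targets and inhibitors (6 rose and 2 fell of 20, adjusted p = 0.118), hedgehog (2 and 1 of 13, 0.685), FGF (2 and 0 of 14, 0.143), collagen processing (3 and 1 of 21, 0.503), glycosaminoglycan synthesis (0 and 1 of 23, 0.215), endoplasmic reticulum stress and secretion (1 and 1 of 22, 0.101), and immediate early and stress (1 and 0 of 16, 0.135). Of these, endoplasmic reticulum stress was called without ImC replicate 1, ImC replicate 2 or MatC replicate 2 (0.0239, 0.0464 and 0.0232), FGF and immediate early without ImC replicate 2 (0.0464 and 0.000904), and Wnt without MatC replicate 3 (0.027). Wnt, FGF and immediate early were also called with library size only (0.00577, 0.0385 and 0.0404). Within them the Wnt-responsive factor Tcf7 rose by 4.87 ± 0.38 and the collagen cross-linking enzyme Loxl4 by 6.04 ± 0.45, while the secreted Wnt inhibitor Sfrp5 fell by 4.58 ± 0.71 on the log2 scale. The hedgehog list's mean and median differed in sign, at 0.35 and -0.70, and the immediate early list had a median of -0.19 against an upward test.

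The largest falls from ImC to MatC included the complement gene C4b, with 1 read in MatC and a MatC level lower by a ratio of 777 (95% counting interval 139 to 30700). Serpina3n, a protease inhibitor, fell by 4.47 ± 0.41 on the log2 scale (adjusted p = 0.000823).

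**Figure D2:**
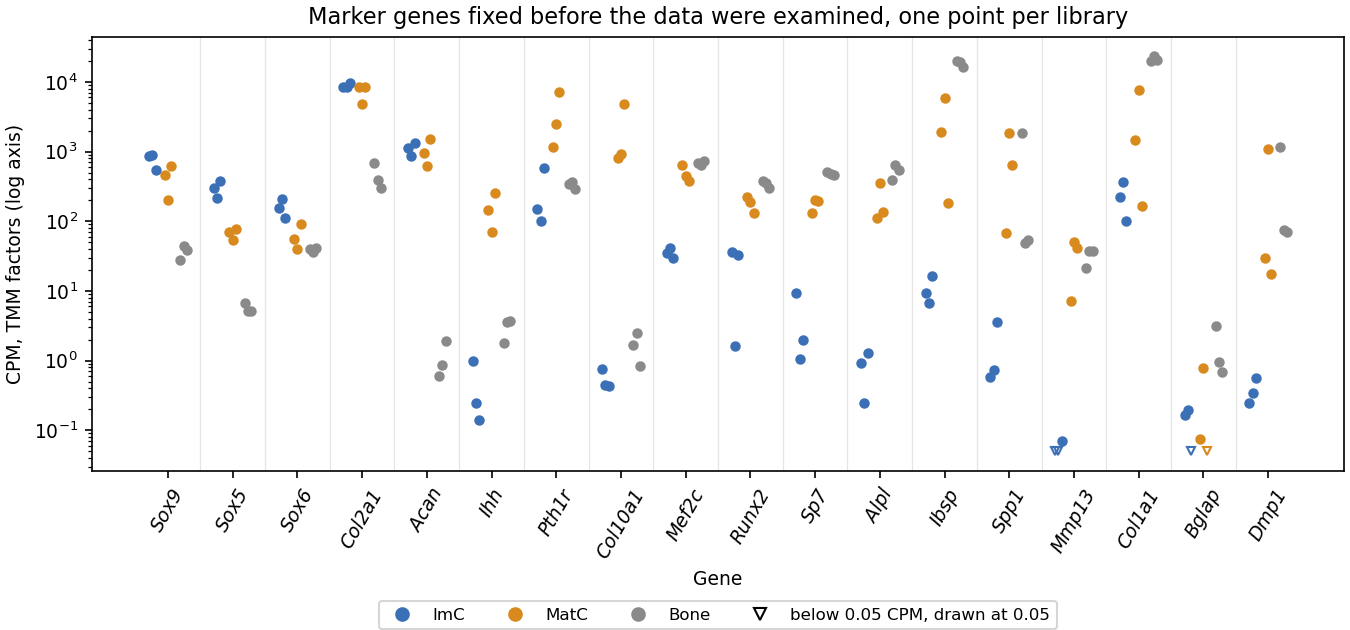
CPM with TMM factors on a log axis for the 18 marker genes, 1 point per library and triangles at 0.05 for lower values. Acan averages 1113 CPM in ImC, 1040 CPM in MatC and 1.12 CPM in Bone, whereas Col10a1 is high in MatC alone.

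In all, 772 genes were higher and 327 lower in MatC than in ImC, of 14257 tested, and 23.9% of genes had groups that did not overlap, against 10% by chance. With library size only, 191 were higher and 167 lower, a share of higher calls of 53.4% against 70.2%, and the median of all genes shifted by -0.53. With only the 2 groups compared, 157 were higher and 48 lower, and 201 of the 1099 calls (18.3%) were kept. Counts fell to 267 and 88 without ImC replicate 1, 457 and 171 without ImC replicate 2, 506 and 119 without MatC replicate 1, 431 and 187 without MatC replicate 2, and 426 and 139, 405 and 136, and 413 and 137 without Bone replicates 1, 2 and 3.

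Bone was compared with MatC to ask what still set osteoblasts apart from mature chondrocytes. The cartilage matrix genes Acan and Col2a1 and the hypertrophy genes Col10a1 and Ihh were lower in bone. Acan (chromosome 7, 79053483 to 79115099) stood at 1.12 ± 0.70 CPM in Bone against 1040 ± 449 CPM in MatC (SD, n = 3), a log2 fold change of -9.83 ± 0.66 (SE, adjusted p = 9.67e-05). Col2a1 (chromosome 15, 97975602 to 98004695), Col10a1 and Ihh fell by 3.98 ± 0.47, 10.36 ± 0.97 and 5.70 ± 0.68 on the log2 scale (adjusted p = 0.00151, 0.000367 and 0.00167). The log2 fold change was -9.02 for Col10a1 without MatC replicate 3 and -10.47 for Acan without Bone replicate 3. The largest rise was Lhx8, a homeobox gene active in the developing jaw (chromosome 3, 154306294 to 154330659), with 2 reads in MatC and a ratio of 589 (95% counting interval 163 to 4870), and the homeobox gene Msx1 rose by 4.80 ± 0.65.

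The bone markers Runx2, Sp7, Alpl, Col1a1 and Ibsp and the transcription factor Mef2c were not called between these tissues. They are not shown to be equal. For each of them every Bone library stood above every MatC library, as for Sp7 at 458.7 to 516.9 against 129.5 to 202.4 CPM. Such groups without overlap made up 35.6% of all genes. In simulated data the test recovered 34.3% of 4-fold changes in this comparison. Log2 fold changes of Bone over MatC were 0.52 ± 0.29 for Mef2c, 0.91 ± 0.76 for Runx2, 1.46 ± 0.63 for Sp7 and 1.37 ± 0.54 for Alpl (adjusted p = 0.311, 0.522, 0.199 and 0.163). Col1a1 averaged 21180 ± 1789 CPM in Bone and 3126 ± 4038 CPM in MatC (adjusted p = 0.151), and Ibsp averaged 18480 ± 1959 and 2681 ± 2955 CPM (adjusted p = 0.107). Bone replicate 1 stood apart in Spp1, at 1853 CPM against 49.1 and 54.7, and in the matrix gene Dmp1, at 1183 CPM against 75.3 and 69.99.

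Immature chondrocyte genes fell in 19 of 25 cases and rose in 0 (22 and 1 adjusted over the list alone; camera adjusted p = 9.34e-26, and adjusted p = 0.0692 with an estimated correlation). Scrg1 had 0 reads in Bone and was at least 687-fold lower. Its fitted log2 fold change, -12.2 with all libraries, was -10.87 without MatC replicate 3. Comp, Matn3 and Col9a3 fell by 10.56 ± 0.90, 10.16 ± 1.06 and 9.19 ± 0.53 on the log2 scale. Hypertrophic chondrocyte genes fell in 8 of 21 cases (10 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.00213, and adjusted p = 0.232 with an estimated correlation). The forkhead factor Foxa3 fell by 8.39 ± 0.69. Without MatC replicate 3 the log2 fold changes of Comp, Matn3 and Foxa3 were -9.73, -9.56 and -7.73, and without Bone replicate 2 that of Matn3 was -10.90. Glycosaminoglycan synthesis genes fell in 6 of 23 cases (8 fell and 1 rose; camera adjusted p = 0.000916, and adjusted p = 0.0692 with an estimated correlation). The sulfate transporter Slc26a2 fell by 2.40 ± 0.31 and the synthase Csgalnact1 fell by 3.22 ± 0.38; both calls ended with library size only (adjusted p up to 0.159 and 0.0866 over all settings). Osteoblast genes rose in 3 of 29 cases and fell in 0 (12 and 0; camera adjusted p = 3.47e-07, and adjusted p = 0.332 with an estimated correlation). Dlx3, Sparc and Serpinf1 rose by 2.22 ± 0.53, 2.71 ± 0.65 and 2.55 ± 0.65, with adjusted p up to 0.14, 0.132 and 0.165 over all settings. Without MatC replicate 2, Dlx3 and Sparc had values of 2.93 and 3.51. Each of these calls ended without any 1 of the Bone libraries or MatC replicate 1. Those of Dlx3 and Sparc also ended without MatC replicate 3, and those of Sparc and Serpinf1 without ImC replicate 1.

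Markers of other cell types were compared between Bone and MatC as well. Osteoclast genes and erythroid genes had 0 called members of 14 and of 10 (0 adjusted over either list alone), with upward list tests (camera adjusted p = 0.00724 and 0.0159, and adjusted p = 0.622 with an estimated correlation for both). Skeletal muscle genes fell in 1 of 15 cases (1 adjusted over the list alone; camera adjusted p = 0.00219, and adjusted p = 0.622 with an estimated correlation). Cell cycle genes fell in 2 of 23 cases (2 adjusted over the list alone; camera adjusted p = 0.00181, and adjusted p = 0.622 with an estimated correlation). Without MatC replicate 1 the osteoclast and erythroid calls ended (adjusted p = 0.129 and 0.114), and without MatC replicate 2 the skeletal muscle call ended (0.0675). Each of those values was the highest over all settings, whose lowest were 4.71e-05, 0.000486 and 4.03e-08. With library size only, the cell cycle and erythroid lists were not called. The other 13 lists were not called. Without MatC replicate 2 the endothelial, macrophage and leukocyte, protease and hypoxia lists were called (0.0332, 0.00433, 0.0326 and 0.0264). The macrophage and protease lists were also called without Bone replicate 1 (0.0231 and 0.0448), hypoxia without Bone replicate 2 (0.0218), and FGF without MatC replicate 3 or Bone replicate 3 (0.0261 and 0.0389). The FGF list and the perichondrium, tendon and fibroblast list were called with library size only (0.0245 for both), and FGF without replicate 3 of both ImC and MatC (0.015). Among these 13 lists the endothelial list had a median of -0.30 and the BMP and TGF-beta list one of -0.20, both against an upward test. The endoplasmic reticulum stress list had a median of -0.10 against a mean of 0.02 and an upward test.

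In all, 194 genes were higher and 669 lower in Bone than in MatC, and 35.6% of genes had groups that did not overlap, against 10% by chance. The share of higher calls was 22.5%, against 40.1% with library size only (119 and 178 calls, with the median of all genes shifted by 1.01), 40% with limma-voom, 36.7% with only these groups and 35.1% without replicate 3 of both ImC and MatC. Counts fell to 20 and 176, 14 and 153, and 25 and 213 without Bone replicates 1, 2 and 3 and to 88 and 401 without MatC replicate 3, and rose to 542 and 1160 without ImC replicate 3.

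Bone was compared with ImC as the ends between which mature cartilage was placed. Genes of bone matrix and bone formation were among those that rose. Ibsp rose from 10.75 ± 4.98 CPM in ImC to 18480 ± 1959 CPM in Bone (SD, n = 3), a log2 fold change of 10.75 ± 1.31 (SE, adjusted p = 0.000582), and Col1a1 rose by 6.53 ± 1.25 (adjusted p = 0.00461). The regulators Sp7 (chromosome 15, 102356606 to 102367182), Runx2 and Mef2c rose by 6.89 ± 0.80, 3.85 ± 0.84 and 4.31 ± 0.33 on the log2 scale (adjusted p = 0.000413, 0.00815 and 5.83e-05). Sox9, Sox5 and Acan fell by 4.38 ± 0.48, 5.70 ± 0.35 and 9.93 ± 0.67 (adjusted p = 0.000291, 2.49e-05 and 4.54e-05). The log2 fold change was 8.36 for Sp7 without ImC replicate 1 and -10.56 for Acan without Bone replicate 3. Genes that mark position in the body also fell: Hoxa9 had 2 reads in Bone and was lower by a ratio of 2710 (95% counting interval 750 to 22400), and the forelimb gene Tbx5 had 2 reads and was lower by a ratio of 2080 (575 to 17200).

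Osteoblast genes rose in 25 of 29 cases and fell in 0 (28 and 0 adjusted over the list alone; camera adjusted p = 1.8e-14), and immature chondrocyte genes fell in 23 of 25 and rose in 0 (23 and 0; 3.66e-19), each with adjusted p = 0.101 with an estimated correlation. Mineralization genes rose in 9 of 16 cases and fell in 2 (9 and 2; camera adjusted p = 0.0011), and glycosaminoglycan synthesis genes fell in 10 of 23 (10; 0.00219), again each with adjusted p = 0.101 with an estimated correlation. Hypertrophic chondrocyte genes split, with 11 higher and 7 lower of 21 (11 and 7; camera adjusted p = 0.0373, and adjusted p = 0.312 with an estimated correlation). The call ended without ImC replicate 2 or MatC replicate 3 (adjusted p = 0.0709 and 0.064, and 0.0146 to 0.0709 over all settings). It also ended with a replicate block and without replicate 3 of both ImC and MatC. Alpl rose by 9.36 ± 0.78, while Foxa3 and the mineralization inhibitor Mgp fell by 8.54 ± 0.69 and 4.52 ± 0.60, the latter by 3.90 without ImC replicate 2. Cell cycle genes fell in 14 of 23 cases (18; camera adjusted p = 2.09e-06) and matrix proteases and inhibitors rose in 6 of 16 (7; 0.00219), each with adjusted p = 0.312 with an estimated correlation. Hypoxia and glycolysis genes fell in 10 of 25 cases and rose in 2 (12 and 2; camera adjusted p = 0.00672, and adjusted p = 0.598 with an estimated correlation), a call that ended without ImC replicate 2 (adjusted p = 0.11, and 0.000262 to 0.11 over all settings). Hk2, the first enzyme of glycolysis, fell by 2.44 ± 0.27.

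The other 9 lists were not called between Bone and ImC. Of these, the Wnt list was called without ImC replicate 2, MatC replicate 2 or any 1 Bone library (adjusted p = 0.0464, 0.0382, 0.0468, 0.04 and 0.0361). The perichondrium and BMP lists were called without ImC replicate 2 (0.0172 and 0.0321) or Bone replicate 1 (0.0199 and 0.0474), and the immediate early list without ImC replicate 2 (0.0105). The perichondrium and Wnt lists were also called with a prior count of 0.5 (0.0499 for both) and with mitochondrial genes left out (0.0467 and 0.0437). The FGF list had a median of 0.46 and a mean of -0.09, and the immediate early list a median of -0.36 and a mean of 0.52. Strong changes of single genes were present: the lysyl oxidase Lox rose by 7.85 ± 1.12 while its relative Loxl3 fell by 4.62 ± 0.54. Without ImC replicate 3, Lox rose by 8.75.

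Markers of other cell types rose in Bone beside these genes. Macrophage and leukocyte genes rose in 12 of 15 cases (12 adjusted over the list alone; camera adjusted p = 1.02e-05), osteoclast genes in 9 of 14 (11; 0.000128) and erythroid genes in 3 of 10 (9; 0.000208), each with adjusted p = 0.312 with an estimated correlation. Endothelial genes rose in 12 of 18 cases (12; camera adjusted p = 0.000128, and adjusted p = 0.37 with an estimated correlation). The osteoclast protease Ctsk rose by 6.77 ± 1.23 on the log2 scale.

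In all, 2039 genes were higher and 2393 lower in Bone than in ImC, and 59% of genes had groups that did not overlap, against 10% by chance. With library size only, 1224 were higher and 849 lower, a share of higher calls of 59% against 46%, and the median of all genes shifted by 0.48. Counts fell to 1345 and 1338, 1222 and 1121, and 1236 and 1195 without Bone replicates 1, 2 and 3.

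**Figure D3:**
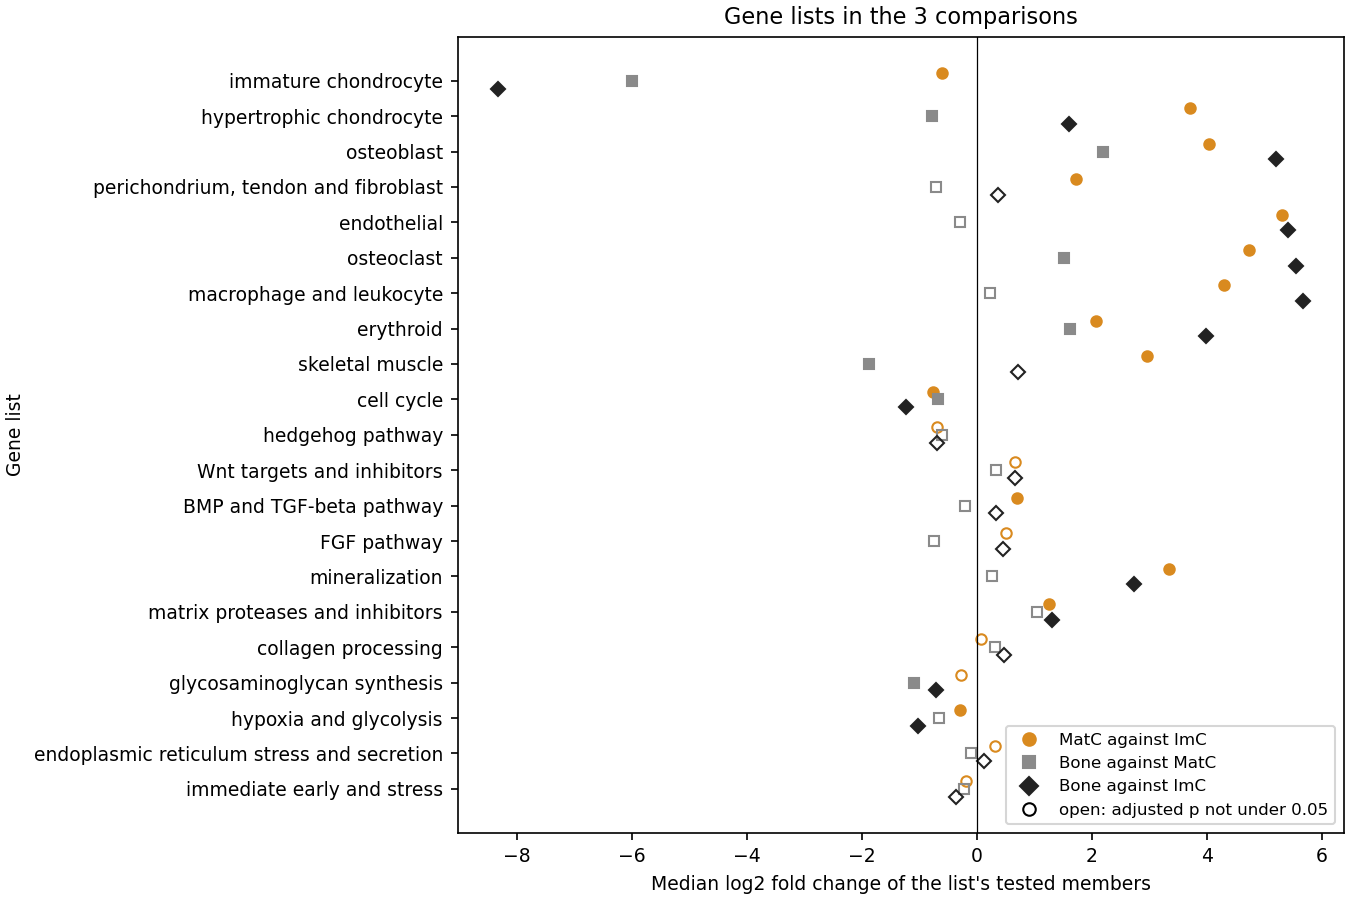
Median log2 fold change of the tested members of each of the 21 lists in the 3 comparisons, with filled symbols for a camera adjusted p under 0.05 at the preset correlation. The immature chondrocyte list lies at -0.60 in MatC against ImC and at -8.33 in Bone against ImC, and the osteoblast list at 4.04 (3.77 with genes of few reads at their bounds) and 5.20.

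The study's title asks whether the cartilage and bone networks combine in mature cartilage by averaging or synergism, so each gene of MatC was placed against both other tissues. Genes above both tissues numbered 64, led by Col10a1, and included Ihh, the secreted protein gene Ccdc80 and the Wnt ligand Wnt5b. Ccdc80 averaged 172 ± 140 CPM in MatC (SD, n = 3) against means of 2.97 in ImC and 3.16 in Bone, a log2 fold change of 5.84 ± 0.64 over ImC (adjusted p = 0.00178) and of -5.75 ± 0.64 for Bone over MatC (adjusted p = 0.000983). It stood at 110.3, 72.61 and 332.4 CPM in MatC replicates 1, 2 and 3, and the values were 4.95 and -4.82 without MatC replicate 3. Col10a1 and Wnt5b also had their highest level in MatC replicate 3. Wnt5b averaged 43.8 ± 25.8 CPM in MatC against 3.48 ± 1.49 and 3.09 ± 0.28. Genes below both numbered 4 and included Dab1, Pcsk2 and Selenbp1, of which Dab1 and Pcsk2 lie outside the naming rule and were chosen after their values were seen. Selenbp1 averaged 3.79 ± 1.61 CPM in MatC against 20.45 ± 4.96 in ImC and 23.24 ± 4.15 in Bone. The number above both was 13 with library size only. It was 32, 114, 24, 16 and 27 without ImC replicates 1 and 3 and Bone replicates 1, 2 and 3. The number below both was 2 without ImC replicate 1, ImC replicate 2 or MatC replicate 3, 1 without any 1 Bone library, 10 without MatC replicate 2 and 16 without ImC replicate 3.

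Genes called at an intermediate level numbered 88, 40 higher in Bone and 48 higher in ImC. Dapk2, a death-associated kinase, averaged 0.180 ± 0.060, 9.18 ± 5.57 and 57.02 ± 7.08 CPM in ImC, MatC and Bone, and Dlx3 averaged 0.222 ± 0.210, 26.8 ± 17.5 and 126 ± 6.56. In the opposite direction, Serpina3n averaged 52.1 ± 12.1, 2.43 ± 0.59 and 0.0181 ± 0.0313 CPM, and Hoxa5 averaged 44.4 ± 2.33, 17.2 ± 1.99 and 0.0368 ± 0.0319. The fall of Hoxa5 from ImC to MatC was not called without ImC replicate 1 or MatC replicate 2, with adjusted p up to 0.101 over all settings. The call of Dlx3 between MatC and Bone ended without MatC replicate 1, MatC replicate 3 or any 1 Bone library (adjusted p up to 0.14). For most genes called between Bone and ImC, MatC was called different from neither: 1283 of the 2039 higher in Bone and 1586 of the 2393 higher in ImC. Among the bone-high genes, MatC was above ImC only for 579 and below Bone only for 131; among the genes high in ImC, it was above Bone only for 498 and below ImC only for 248. Intermediate genes high in Bone numbered 25, 78, 18, 4, 1 and 6 without ImC replicates 1 and 3, MatC replicate 1 and Bone replicates 1, 2 and 3. Those high in ImC numbered 11, 75, 15, 14, 8, 9 and 16 without ImC replicates 1 and 3, MatC replicates 1 and 2 and Bone replicates 1, 2 and 3. With library size only the numbers were 10 and 9.

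Of the 772 genes higher in MatC than in ImC, 625 (81%) were also higher in Bone than in ImC, and of the 327 lower genes 296 (90.5%) were also lower; 13 were called in opposite directions. Independent lists would share 110 and 54.9. The 3 ImC libraries serve both comparisons and are too few to split, so the part of the excess that comes from shared controls was not measured. In 20 simulations of unchanged groups the median number of calls was 0 in either comparison, which gives no reference for shared calls. The 921 shared calls became 310 and 561 without ImC replicates 1 and 2, 527 and 503 without MatC replicates 1 and 2, and 462, 444 and 442 without Bone replicates 1, 2 and 3.

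The median position of MatC was 0.53 (quartiles 0.30 to 0.75 over 4169 genes), where 0 is ImC and 1 is Bone, and 84.9% of genes lay between 0 and 1. It was 0.65 for genes higher in Bone and 0.42 for genes higher in ImC. These group values use fitted log2 fold changes. A per-library position used log2 CPM with a prior count of 2 instead, and was 0.64, 0.50 and 0.29 in MatC replicates 1, 2 and 3 (SD 0.18). Simulated libraries equal to ImC read 0.0442 and 0.0555 for these gene sets, libraries equal to Bone read 0.948 and 0.959, and a linear mixture with 30% bone RNA read 0.492 and 0.216. The simulated mixture thus gave the same order of the gene sets as the group medians. By the per-library measure, genes higher in Bone read 0.66, 0.69 and 0.32 in MatC replicates 1, 2 and 3, and genes higher in ImC 0.63, 0.37 and 0.28. The simulated positions above were not computed with that measure. The order was thus marked in replicate 2 and slight in replicates 1 and 3.

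**Figure D4:**
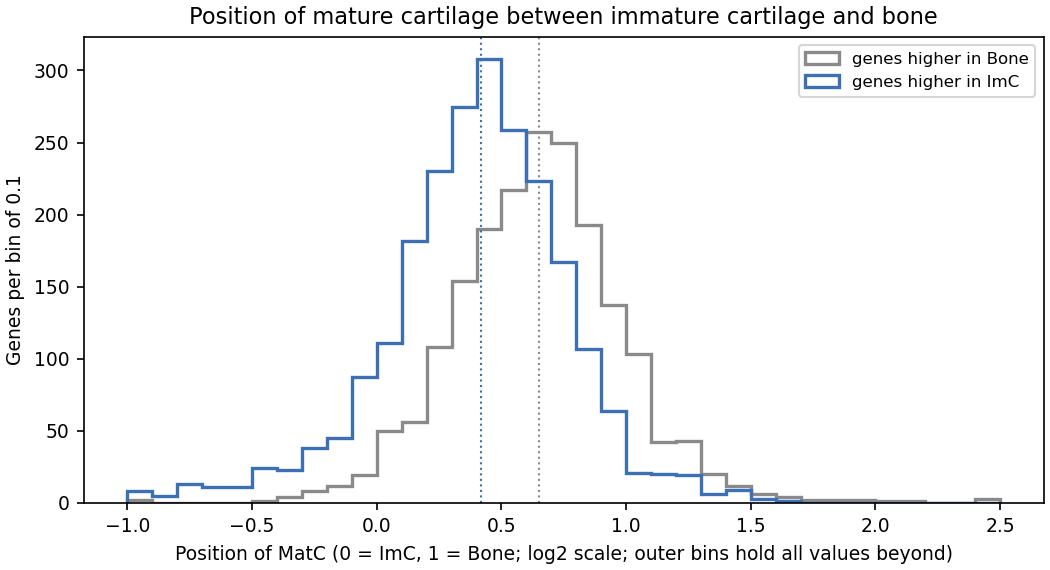
Histogram of the position of MatC for genes called between Bone and ImC, in bins of 0.1 on the log2 scale, with dotted lines at the medians. The medians are 0.65 for genes higher in Bone and 0.42 for genes higher in ImC.

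**Figure D5:**
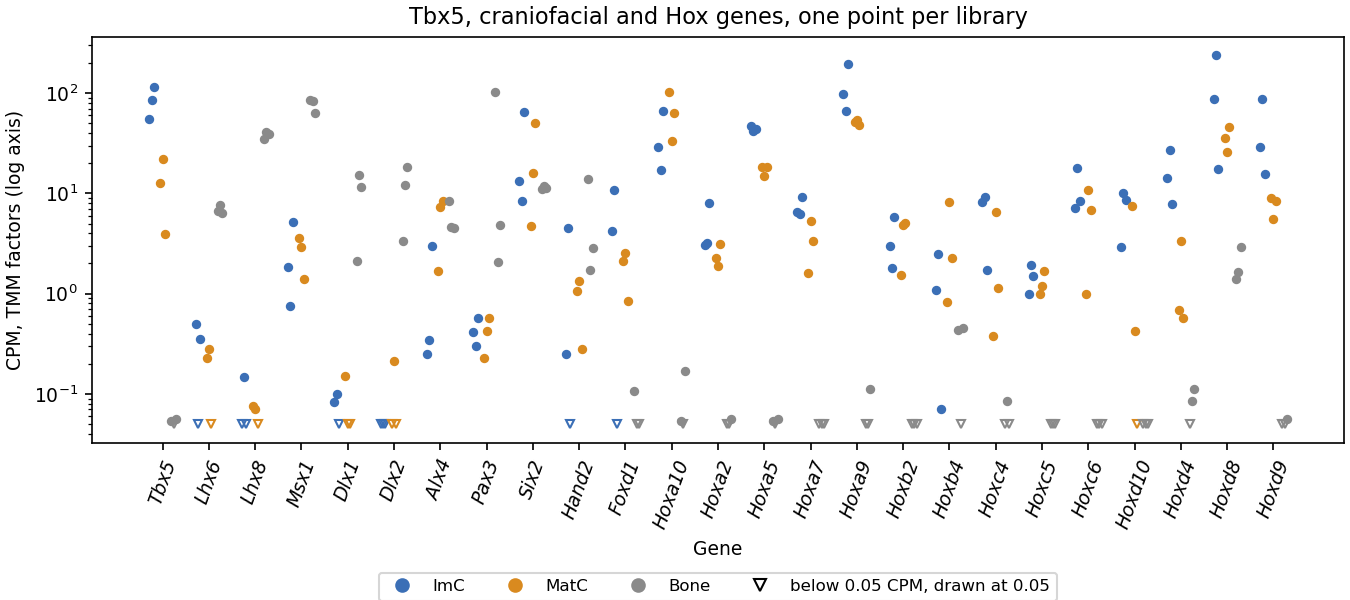
CPM with TMM factors on a log axis for Tbx5, craniofacial genes and Hox genes, 1 point per library and triangles at 0.05 for lower values; this set was drawn up after some of the values were seen. Hoxa9 and Tbx5 stand below 0.2 CPM in every Bone library, whereas Lhx8 stands at 34.8 to 41.3 CPM there.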

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

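Leaving out mitochondrial genes, using the authors' factors, and leaving out replicate 3 of both ImC and MatC were chosen after seeing the data; the other alternatives were planned. Counts below are genes called, and a value is printed where it left the main count by more than 1.5 times. The cause was not tested for any of these changes except where an alternative by construction tests fewer genes, fewer libraries or a stricter threshold.

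With each library left out in turn, genes higher in MatC than ImC (772 in the main test) ranged from 267 to 949 and genes lower (327) from 88 to 342. Genes higher in Bone than MatC (194) ranged from 14 to 542 and genes lower (669) from 153 to 1160. Genes higher in Bone than ImC (2039) ranged from 1222 to 2618 and genes lower (2393) from 1121 to 2790. Genes above both tissues in MatC (64) ranged from 16 to 114 and genes below both (4) from 1 to 16. Intermediate genes ranged from 1 to 78 where Bone was higher (40) and from 8 to 75 where ImC was higher (48), and shared calls (921) from 310 to 1096. The median position of MatC ranged from 0.45 to 0.59 over all genes, 0.57 to 0.70 for genes higher in Bone and 0.34 to 0.50 for genes higher in ImC, within 1 SD of the libraries in every case.

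With library size only, the numbers higher and lower were 191 and 167 for MatC against ImC, 119 and 178 for Bone against MatC, and 1224 and 849 for Bone against ImC. That scaling gave 13 genes above both, 2 below both, 10 and 9 intermediate, and 301 shared calls. DESeq2 gave 1452 and 805 for MatC against ImC, 620 and 1332 for Bone against MatC, 209 above both, 24 below both, 130 intermediate in each direction and 1737 shared. With limma-voom 426 genes were lower in Bone than MatC. With no filter 1225 genes were higher in MatC than ImC, 445 higher and 1059 lower in Bone than MatC, 176 above both, 14 below both, and 144 and 91 intermediate. With at least 10 CPM in 3 libraries 436 genes were higher in MatC than ImC, 1294 higher in Bone than ImC, 31 above both and 1 below both.

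Testing against a 1.5-fold change gave 505 and 132 genes for MatC against ImC, 71 higher in Bone than MatC, 39 above both, 16 and 15 intermediate, and 536 shared. An adjusted p of 0.01 gave 157 and 35 for MatC against ImC, 16 and 189 for Bone against MatC, 905 and 1030 for Bone against ImC, 15 above both, 1 below both, 1 and 4 intermediate, and 166 shared. With only the 2 groups compared, MatC against ImC gave 157 and 48, Bone against MatC gave 442 higher, and 162 were shared; the counts above both, below both and intermediate were not run this way. A replicate block gave 191 genes lower in MatC than ImC and 2 below both. Without replicate 3 of both ImC and MatC, the counts were 1327 and 581 for MatC against ImC, 564 and 1041 for Bone against MatC, 150 above both, 16 below both, 157 and 131 intermediate, and 1642 shared.

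No gene called in the main test was called in the opposite direction under any alternative. The reversed value was Hk2 in Bone against MatC, at 0.001 with library size only, where it was not called. Of the 298 named gene results, size factors ended 0 calls, upper-quartile factors 1, leaving out mitochondrial genes 1, the authors' factors 6, a replicate block 21, limma-voom 29, only the 2 groups 35, a 1.5-fold threshold 38, library size only 81 and an adjusted p of 0.01 ended 105. Leaving out ImC replicates 1, 2 and 3 ended 51, 24 and 21 calls, MatC replicates 39, 31 and 28, and Bone replicates 66, 69 and 61. Named calls held in every setting in 37 of 87 cases for MatC against ImC, 27 of 72 for Bone against MatC and 80 of 113 for Bone against ImC. Of the 34 list calls, library size only ended 2, the replicate block 1 and an estimated correlation 33. Of the lists not called, library size only made 5 called, leaving out mitochondrial genes 2 and a prior count of 0.5 made 2. Without replicate 3 of both ImC and MatC, 1 list call ended and 1 list became called. Whether replicate numbers pair the libraries was settled only in part. Sex-linked reads argue against a shared animal for MatC and ImC of number 2, where Xist had 2 and 7314 reads. They also argue against it for Bone of number 3, with 3 Xist reads against 6730 in ImC and 1430 in MatC. Ddx3y had the opposite pattern. These reads do not bear on a pairing of another kind. Deviations correlated across genes at 0.33, -0.056 and 0.32 between MatC and ImC of numbers 1, 2 and 3. They correlated at -0.16 to 0.081 for the other tissues, and 4 of 9 libraries correlated best with their own number. A pairing of the cartilage libraries of numbers 1 and 3 is therefore not excluded. With a replicate block, 681 of the 1099 calls of MatC against ImC (62%) were kept. Depth limits MatC replicate 3 most, where 3 reads equal 0.849 CPM.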

Other observations

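The tests on bone RNA, mixtures, Hox genes, body site, imprinted genes and mitochondrial reads were chosen only after the results they concern were seen. Those on bone RNA and mixtures were also revised. A first version on all bone-high genes with TMM factors had excluded bone RNA in every MatC library; more filters and scalings were then added, and settings in which a library shows no rise were afterwards left out of the verdict. In addition, a first version of the mixture test had excluded mixing before simulated mixtures showed that its shares are biased. The counts of other groupings were planned; earlier random draws of the same number of regroupings also gave shares under 0.05 for genes above both.

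Genes that mark position along the body differed between Bone and both cartilage groups, whereas fewer of them were called between the cartilage groups. Of 14 Hox genes tested, 13 were lower in Bone than in ImC and 12 lower than in MatC, with median log2 fold changes of -8.64 and -8.15 (-7.41 and -6.13 with genes of few reads at their bounds, and -8.3 and -7.35 with library size only). Of 10 craniofacial genes tested from a list of 15, Lhx6, Lhx8, Msx1, Dlx1, Dlx2 and Pax3 were higher in Bone in both comparisons, and Foxd1 was lower than in ImC. In MatC against ImC, 3 of the 14 Hox genes were lower and 0 higher, and 0 craniofacial genes were called. Among all 14257 genes tested, 327 were lower in that comparison. The Hox median was -1.15, against 0.029 for all genes (-1.7 with library size only, which shifted the median of all genes by -0.53). Of the 3, Hoxd9 was not called without ImC replicate 2 (adjusted p = 0.0973). Hoxa5 was not called without ImC replicate 1 or MatC replicate 2. Tbx5 fell by 2.70 ± 0.54 from ImC to MatC (adjusted p = 0.0172), and by 3.30 without MatC replicate 2. That call ended without MatC replicate 1, with library size only and with only the 2 groups compared (adjusted p up to 0.0715 over all settings). Pax3 stood at 102 CPM in Bone replicate 1 against 2.06 and 4.79 in the other two, and its call over MatC ended without Bone replicate 1 or any 1 MatC library (adjusted p = 0.03 with all libraries, and up to 0.258 over all settings).

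Too few reads do not explain the low Hox counts, since Bone libraries held at most 1.26% of the Hox reads expected at the cartilage level, with 36, 21 and 70 reads against 5774, 3651 and 5551. A candidate explanation is that bone was taken from the head and cartilage from elsewhere, for which the median of -8.15 and the craniofacial genes have the predicted direction. A difference between tissues at a single site stays open, because 0 bone groups of another site are in the series and tissue and site are confounded. The labels name no site, so every difference between groups in the report, those between ImC and MatC included, may include a difference of site.

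Genes high in Bone were raised in MatC, and RNA from bone in the cartilage samples is a candidate explanation. For each MatC library, the median share of the bone excess over ImC, across bone-high genes, was set against the highest share of Col1a1, Col1a2 and Ibsp, abundant bone transcripts that bone RNA would bring along. In MatC replicate 1 the lowest median over 3 gene filters and 3 scalings was 21.2% against 8.87%, so RNA with the profile of these Bone libraries does not account for the whole rise there. The same holds for MatC replicate 3 with TMM factors (5.29% to 11.7% against 0.942%) and the authors' factors (at least 4.65% against 0.853%), whereas library size only gave -13.5% to -0.112% and so no rise to explain. In MatC replicate 2 the question stays open, with 35.5% to 43.4% against 35.8% for TMM factors and a lowest value of 2.55% against 14.2% for library size only.

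A mixture of RNA like ImC and RNA like Bone also stays open for the intermediate position of MatC. The bone share read from genes high in ImC exceeded that read from bone-high genes by 17.6 to 27.7 percentage points in MatC replicate 2 with TMM factors, 21.7 to 31.1 with the authors' factors and 70 to 102 with library size only, and simulated mixtures gave gaps of 13.2 to 27. In MatC replicates 1 and 3 the gaps with TMM factors were 41.9 to 49.5 and 35.4 to 41.8, above the simulated range. The gaps under the other scalings lay above it too, but it was simulated with TMM factors only and is no reference for them. The gaps with TMM factors in replicates 1 and 3 go against a simple mixture, but a bound from simulated settings does not exclude it.

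The share of mitochondrial reads was 44.1% in ImC, 61.7% in MatC and 8.01% in Bone, and was tested as a source of distorted scaling. With mitochondrial genes left out, at least 96.3% of the genes called in each comparison with Bone kept their call. That setting moved the median of all genes by at most 0.02, since TMM factors trim extreme genes. Scaling that no longer held the mitochondrial reads thus gave nearly the same calls. These values argue against distortion of the TMM scaling by those reads themselves. With library size only, which carries the mitochondrial share, 29.8% and 46% of the calls of Bone against MatC and ImC were shared. Differences between the samples that may go with that share, RNA quality among them, were not tested and stay open.

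A list of imprinted genes had lower medians in Bone. The list of 50 was drawn up after several had been seen, so its tests partly restate what prompted them. Of 44 tested, 24 were lower and 3 higher in Bone than in ImC, with a median of -2.28 (-1.71 with library size only; camera adjusted p = 1.6e-06, and adjusted p = 0.0428 with an estimated correlation). Against MatC, 15 were lower and 1 higher, with a median of -1.35 (camera adjusted p = 8.94e-08, and adjusted p = 0.0428 with an estimated correlation), and -0.39 with library size only, where the median of all genes shifted by 1.01. In MatC against ImC, 5 were lower and 2 higher, with a median of -0.63 (-1.06 with library size only; camera adjusted p = 0.00365, and adjusted p = 0.138 with an estimated correlation). The genes lower in both comparisons with Bone included H19, Dlk1, Meg3, Peg3 and Plagl1.

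Sex-linked reads differed within groups. Xist had 6, 7314 and 6730 reads in ImC, 1, 2 and 1430 in MatC and 5, 2685 and 3 in Bone, and Ddx3y had reads in the opposite pattern. The libraries of a group thus did not all come from 1 animal, and the sexes were not balanced between ImC and the other groups. The hemoglobin gene Hba-a1, whose reads are shared with its paralogs, stood at 361 CPM in ImC replicate 3 against 1.67 and 6.21 in the others.

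For each pairwise comparison, 1 of the 10 splits of the 6 libraries, the real one, gave as many calls (1099, 863 and 4432), and the highest other gave 0; 10 splits are too few for a share under 0.05. Of 100 regroupings of the 9 libraries drawn from 840, 2 gave as many genes above both as the real 64, a share under 0.05. The highest other gave 87 and kept the 3 ImC libraries together in the place of MatC, with MatC and Bone libraries mixed in the other groups. The exchange of ImC and MatC as whole groups was not among those drawn but 296 genes were lower in both MatC and Bone than in ImC, so ImC in the place of MatC would exceed the 64. The share therefore does not set MatC apart from the other groups. It does not decide whether chance accounts for the 64 genes either, because regroupings that mix tissues in all 3 groups could hardly reach that number. For the 88 intermediate genes, 1 of 100, the real one, gave as many, and the highest other of those drawn gave 0. Splits that mix tissues gave 0 calls in every pairwise comparison as well. Regroupings that mix tissues could therefore hardly reach 88, so this share does not decide whether chance accounts for these genes.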
